A study of Pichia kudriavzevii with 6 samples.

How the data were processed

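RNA for 6 libraries of Pichia kudriavzevii strain CY902 with a URA3 deletion was sequenced, 2 libraries for each of 3 media (SoleG, GS and SoleS). The labels' protocols give a preculture of 24 hours, an inoculum at an optical density of 0.1 and a harvest optical density of 2 to 3. Cells were washed and moved into 50 mL of test medium at pH 5.0, then shaken at 250 rpm and 30 °C for 3 hours. RNA was prepared with Trizol and a column with DNase treatment, and libraries were made by Illumina protocols. Bowtie2 2.2.5 is named in the submitters' processing notes. The counting tool, its handling of strand and of reads with several matches, the genome build and the annotation are not given in the sources used here. Reads shared between similar or overlapping genes may therefore have been split or dropped in a way that could not be checked.

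Each library had 1 file with 5464 genes and, per the file headers, the coding length, a raw count and an FPKM value per gene. The counts deposited by the authors are whole numbers and sum to between 6024768 and 6959188 per library. All 5464 coding lengths are multiples of 3 and the same in every file. The FPKM values deposited by the authors equal the count divided by the coding length and by the library's total count in 5 of the 6 files. In the file of GS replicate 2 they were computed with 6744749, the total of GS replicate 1, in place of its own 6269038, so every FPKM value of that library is 0.929 times what its own total gives. Counts are not affected and were used for all main results. Files of 2 libraries ended in 5 blank lines, which were dropped. No column belonged to another sample.

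Gene IDs have the form PK followed by a number and are not paired with names in the files. The reference table, of assembly ASM305444v1 of strain CBS573, matched 0 of the 5464 IDs. The planned tests of 20 gene lists (camera and fry), the carboxylate transporter genes and the check of URA3 in every library were therefore not run. The rule for named genes, fixed before the data were examined together with the tests and the other settings tried, then allows 2 genes up and 2 genes down per comparison. These have the largest fold changes among genes with an adjusted p below 0.05, a mean of at least 50 CPM in the higher group and both libraries of one group above both of the other.

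Genes with low counts were removed with edgeR's filterByExpr, which left 5280 genes and removed 184 that held 0.00351% of the counts. Libraries were scaled with TMM factors (0.957 to 1.08), and 1 model with the 3 groups was fitted to all 6 libraries with edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit, glmQLFTest), leaving 3 residual degrees of freedom. Called genes have a Benjamini-Hochberg adjusted p below 0.05 within a comparison. CPM values are after TMM scaling, and shares of counts use the full totals. The standard error of a log2 fold change is its size divided by the square root of the test's F statistic. It is narrower than counting error for very large changes that rest on few counts in 1 group. An exact counting interval is given for these in its place. An exact test of 1 gene on 2 against 2 libraries cannot go below p = 0.333, so p-values come only from the model across genes. The exact counting interval of a ratio of counts is a Clopper-Pearson interval at 95%, and arises from counting error only.

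The test was checked on simulated counts with each gene's mean over all 6 libraries, the real library sizes and spread, and 200 changed genes per comparison. Directions were drawn at random. Most genes were called in the real comparisons with SoleS, so the rates of false calls below may not carry over to them. For SoleS against SoleG (5271 genes) edgeR recovered 96% of 1.5-fold, 94% of 2-fold and 100% of 4-fold changes, with 5.34% false calls. For GS against SoleG (5267 genes) the values were 86%, 94%, 100% and 4.04%. For SoleS against GS (5265 genes) they were 72%, 98%, 100% and 3.65%. For GS against SoleG, 200 changed genes were also placed in the lowest or the highest 20% by mean CPM. Of 1.5-fold changes 27% (5268 genes) and 100% (5267 genes) were recovered, and of 2-fold changes 83% and 100% (5270 genes each). The shared SoleG libraries were modelled with 20 simulations in which all 6 libraries came from the SoleG means. A further 20 were run for each library left out, and 20 for each split of the SoleG libraries. The other settings fixed beforehand were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter, a filter of 50 counts in 2 libraries, fits to the 2 groups compared, the replicate number as a block, each library left out, and limma on log2(FPKM + 1) or log2(FPKM + 0.1). FPKM values were kept where at least 1 in 2 libraries, or unfiltered. Total-count scaling, FPKM recomputed from each library's own total removal of a trend with coding length and, for the overlap, a different SoleG library for each comparison were added, as was a grouping by abundance with SoleS and SoleG weighed alike, after the data were seen.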

Results

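Gene expression was measured by RNA sequencing in the yeast Pichia kudriavzevii, an acid-tolerant species used to make organic acids, after a change of carbon source. All cells were of strain CY902 carrying a deletion of URA3, the orotidine phosphate decarboxylase gene of uracil synthesis and a common selection marker. Washed cells from a glucose culture were moved to fresh medium at pH 5.0 and collected after 3 hours. The medium held glucose at 2% (SoleG), glucose at 2% together with succinic acid at 2% (GS), or succinic acid at 2% without glucose (SoleS). Each group had 2 libraries. The series aims to identify transporters of dicarboxylic acids such as succinic acid.

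The count totals were 6657238 and 6648094 in SoleG, 6744749 and 6269038 in GS, and 6959188 and 6024768 in SoleS. Of 5464 genes, between 5320 and 5331 had a count in each single library, and 121 had no count in all 6. A count of 0 allows up to 3 counts, or 0.416 to 0.513 CPM (counts scaled to a common library total) depending on the library. These limits, and all counting intervals given here, cover counting error only. Genes carry IDs of the form PK0942, and the files do not pair them with names. No ID matched the reference gene table, so URA3, the transporter genes and the 20 gene lists planned for pathways could not be looked up. The results below describe genes by ID, coding length and response. Copies that are nearly identical could not be recognised either, and their counts are uncertain for the named genes too.

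Libraries of the same medium lay close together and SoleS stood apart from both glucose media. The Pearson correlation of log2 CPM across genes was 0.993 within SoleG, 0.993 within GS and 0.994 within SoleS. It was 0.966 to 0.974 between SoleG and GS libraries, 0.732 to 0.736 between SoleG and SoleS, and 0.725 to 0.730 between GS and SoleS. Genes are not independent replicates in these values. Replicates of a group were distinct libraries, since their counts differed by 5.69, 2.83 and 3.98 times the sampling noise per gene in SoleG, GS and SoleS. The labels do not say whether they came from separate cultures, so the p-values measure only the spread between these libraries.

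The comparison of SoleS with SoleG asked what changed when succinic acid replaced glucose as the only carbon source. Most of the measured transcriptome changed. Of 5280 genes tested, 2016 were higher and 2162 lower in SoleS, and 976 of the higher and 838 of the lower genes changed at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). PK0942, with a coding length of 1260 bases, rose from 1.39 ± 0.97 CPM in SoleG to 6330 ± 57 CPM in SoleS (SD, n = 2). Its log2 fold change was 12.12 (edgeR adjusted p = 1.24e-25), on 20 counts in SoleG and 79164 in SoleS. The ratio of these counts, scaled by library size, had an exact counting interval of 2918 to 7379. The SoleG counts were 15 in replicate 1 and 5 in replicate 2, and without replicate 1 the log2 fold change was 13.08. PK1877, of 2250 bases, rose from 1.61 ± 0.27 to 4178 ± 205 CPM, a log2 fold change of 11.32 (edgeR adjusted p = 1.24e-25). It had 23 counts in SoleG, and its count ratio had an exact counting interval of 1728 to 4092. PK2426, of 1641 bases, fell from 11039 ± 543 to 24.8 ± 3.4 CPM, a 447-fold decrease (log2 fold change -8.80 ± 0.12 SE; edgeR adjusted p = 1.24e-25). PK4657, of 1233 bases, fell from 626 ± 48 to 1.91 ± 0.28 CPM, a 323-fold decrease (log2 fold change -8.34, edgeR adjusted p = 2.40e-23). It had 24 counts in SoleS, and its decrease had an exact counting interval of 219 to 509.

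A small group of strongly induced genes came to hold a large share of the SoleS counts. The 65 genes at least 16-fold higher in SoleS than in SoleG took 28.2% ± 0.1 of the counts in SoleS, 0.482% ± 0.019 in SoleG and 0.611% ± 0.011 in GS (SD, n = 2). The 20 of them at least 128-fold higher took 15.7% ± 0.3 in SoleS, 0.0291% ± 0.0021 in SoleG and 0.0194% ± 0.0001 in GS. The gene most abundant in SoleS, of 1134 bases, accounted for 4.95% ± 0.16 of the SoleS counts, at 51355 ± 1092 CPM against 47.8 ± 1.4 CPM in SoleG. It was singled out after its values were seen. The 42 genes at least 16-fold lower in SoleS fell from 9.42% ± 0.25 of the counts in SoleG to 0.287% ± 0.004. These groups were chosen on the same libraries, so their shares describe the change and do not test it.

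Changes in SoleS were spread over all abundances, with opposite balance at the 2 ends. Among the 20% of genes with the lowest mean CPM over all libraries, 524 were higher and 209 lower in SoleS than in SoleG. Among the 20% with the highest mean CPM, 351 were higher and 603 lower. The mean over all libraries weighs the glucose media more than SoleS, which can add to this lean. With SoleS and SoleG weighed alike, 498 were higher and 252 lower in the lowest 20%, and 393 higher and 541 lower in the highest. Long genes also leaned downwards, with a median log2 fold change of -0.29 in the 20% with coding lengths of 2109 to 15027 bases and 0.09 in the 20% of 63 to 651 bases. Scaling by total counts alone, in place of TMM factors, moved the median of all genes from -0.03 to -0.18 and the genes changed at least 2-fold from 976 higher and 838 lower to 809 higher and 1038 lower. Upper-quartile factors moved them the other way, to 1118 higher and 716 lower. Over all calls, upper-quartile factors gave 2263 higher and 1924 lower genes, and total counts gave 1744 higher and 2456 lower.

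**Figure D1:**
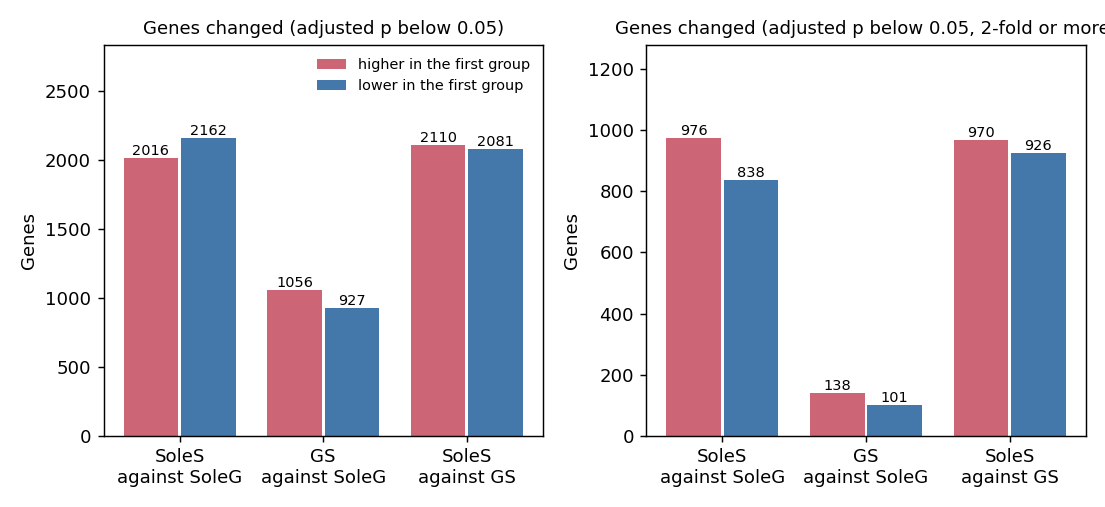
Number of genes higher (red) or lower (blue) in the first-named group of each comparison, at an edgeR adjusted p below 0.05 (left) and also at least 2-fold changed (right). GS against SoleG had 239 genes changed at least 2-fold, against 1814 for SoleS against SoleG and 1896 for SoleS against GS.

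The comparison of GS with SoleG asked what changed when succinic acid was added while glucose was present. An effect of succinic acid itself could not be told apart from that of other medium changes that came with it at the same pH. Here the changes were fewer and smaller. Of 5280 genes, 1056 were higher and 927 lower in GS (edgeR, adjusted p below 0.05), and 138 and 101 of these changed at least 2-fold. The median size of the called changes was 0.47 on the log2 scale, against 0.89 for SoleS against SoleG. PK3316, of 1605 bases, rose from 47.6 ± 10.5 CPM in SoleG to 267.9 ± 9.9 CPM in GS (SD, n = 2), a log2 fold change of 2.49 ± 0.11 (SE; edgeR adjusted p = 3.94e-14), yet was at 10.2 ± 3.5 CPM in SoleS. PK4701, of 1776 bases, rose from 26.3 ± 7.4 to 142.4 ± 3.7 CPM, a log2 fold change of 2.44 ± 0.12 (SE; edgeR adjusted p = 1.55e-13), and was higher still in SoleS at 719 ± 49 CPM. PK5146, of 699 bases, fell from 105.0 ± 12.8 to 4.46 ± 0.65 CPM, a 23.5-fold decrease (edgeR adjusted p = 1.92e-15). PK5147, of 885 bases, fell from 111 ± 12 to 9.62 ± 0.78 CPM, an 11.6-fold decrease (edgeR adjusted p = 1.16e-14). Both were also low in SoleS, at 1.22 ± 0.45 and 3.50 ± 1.34 CPM.

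The balance of directions between GS and SoleG depended on the scaling. With total counts in place of TMM factors, the median of all genes moved from -0.01 to -0.15 on the log2 scale, and 697 genes were higher and 1711 lower in GS. At 2-fold or more the split moved from 138 higher and 101 lower to 88 higher and 135 lower. The share of genes called rose from 22.0% in the lowest 20% by mean CPM to 60.7% in the highest. In simulated counts for this comparison, 1.5-fold changes were recovered in 27% of 200 genes in the lowest 20% and in 100% of 200 in the highest, so small changes of weakly expressed genes were less detectable. Whether abundant genes also changed more was not separated from this.

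**Figure D2:**
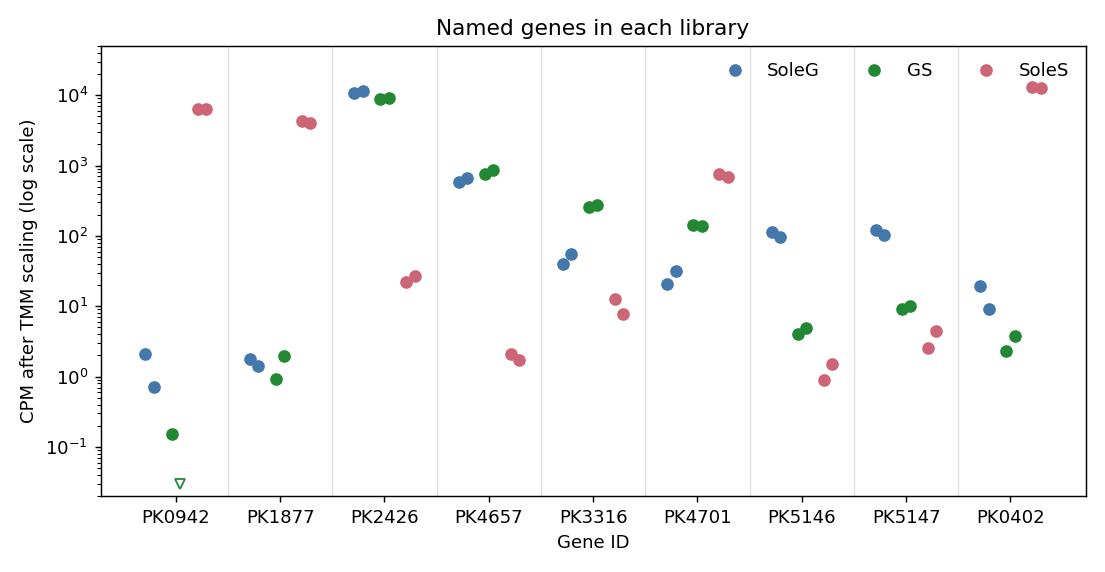
CPM after TMM scaling, on a log scale, of the named genes in each library, with SoleG in blue, GS in green and SoleS in red, 1 point per library. The open triangle at the bottom marks PK0942 in the GS library with a count of 0, and PK0942 lies at 6330 ± 57 CPM in SoleS.

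The comparison of SoleS with GS asked what the absence of glucose changed when succinic acid was present in both media. It resembled the comparison with SoleG in size, with 2110 genes higher and 2081 lower in SoleS (edgeR, adjusted p below 0.05), of which 970 and 926 changed at least 2-fold. The split stayed near even under RLE and total-count scaling, while upper-quartile factors gave 2362 higher and 1841 lower, with 1147 and 790 at 2-fold or more. PK0942 was again the most strongly induced, with 1 count in the 2 GS libraries together and 79164 in SoleS. The ratio of these counts, scaled by library size, was 79757, with a 95% exact counting interval of 14314 to 3150260. The log2 fold change in edgeR was 15.97, and it was 15.16 without GS replicate 2. Without GS replicate 1, which held the count, it was 18.34. The GS count left was then 0, so the data set no upper limit to that value. PK0402, of 1683 bases, rose from 3.04 ± 1.04 CPM in GS to 12827 ± 48 CPM in SoleS (SD, n = 2), a log2 fold change of 12.05 (edgeR adjusted p = 3.99e-24). It had 38 counts in GS, and its count ratio had a 95% exact counting interval of 3100 to 6014. PK4657 was lower in SoleS than in GS by 419-fold (edgeR adjusted p = 8.08e-24) and PK2426 by 362-fold (edgeR adjusted p = 1.59e-25). PK4657 had 24 counts in SoleS, and its decrease had a 95% exact counting interval of 283 to 659.

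Both comparisons against SoleG were then set side by side, to see whether succinic acid with glucose changed genes in the direction of succinic acid alone. Over all called genes the directions were nearly balanced under TMM scaling. Of 1983 genes changed in GS, 1686 also changed in SoleS, 867 of them in the same direction and 819 in the opposite one, or 51.4% in the same direction. Independent lists of these sizes would share 783 calls in the same direction and 786 in opposite directions. With total-count scaling, 1175 genes changed in the same direction and 851 in the opposite one (58.0% the same), where independent lists would share 1026 in the same direction. Without GS replicate 2 the TMM counts were 587 and 594. In 20 simulations of groups with no change against the same number of SoleG libraries, 66.1% of genes had fold changes of the same sign, against 49.8% observed. No gene changed in the simulations, so the simulated share comes from noise of the shared SoleG libraries alone. It is therefore not a chance level for the observed share. The simulated groups shared no calls in the same direction, so they give no chance value for the shared calls. The log2 fold changes had a Pearson correlation of 0.08 across genes. Their covariance was 0.0554, against 0.0111 ± 0.0006 (SD) from the shared SoleG libraries in the simulations, which left 0.0443. Simulated counts were filtered again, so genes scarce in SoleG that passed the real filter through SoleS could drop out of the simulated value. What was left may therefore still hold noise of the shared SoleG libraries. With the simulations repeated for each set of libraries, the covariance less its simulated value was 0.0231 without GS replicate 2, 0.0657 and 0.0683 without SoleG replicate 1 or 2, and 0.0570 and 0.0329 with a different SoleG library for each comparison. The simulated correlation was 0.48, again from shared noise alone, and is not a chance level for the observed 0.08.

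Genes that rose at least 2-fold in GS mostly rose in SoleS too, while genes that fell at least 2-fold were split between both directions. Of the 138 genes at least 2-fold higher in GS, 107 were also higher in SoleS, 26 were lower and 5 were not called, where independent lists would give 52.7 higher and 56.5 lower. Their median log2 fold change in SoleS was 1.91. PK4701 was among the 107 and PK3316 among the 26. Of the 101 genes at least 2-fold lower in GS, including PK5146 and PK5147, 46 were also lower in SoleS and 39 were higher, where independent lists would give 41.4 and 38.6. The SoleG libraries were shared, so part of the excess over independent lists may come from them. The numbers for independent lists, here and above, also leave out that calls and directions in SoleS varied with abundance. Set against a different SoleG library each, 1 per comparison, 112 of 142 genes at least 2-fold higher in GS were higher in SoleS with SoleG replicate 2 as the control for GS, and 124 of 165 with replicate 1, where independent lists would give 51.4 and 60.2. The count of 107 became 72 of 88 genes with edgeR on total counts and 51 of 62 with limma on the deposited FPKM values, a fit that differs in several choices at once.

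**Figure D3:**
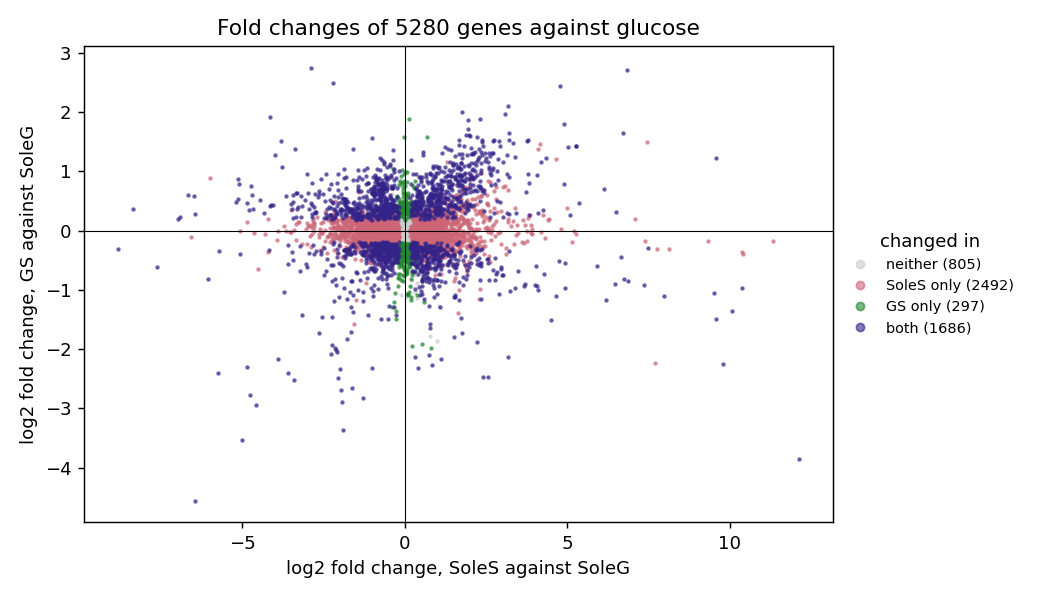
Log2 fold change against SoleG in SoleS (horizontal) and in GS (vertical) for the 5280 genes tested, 1 point per gene, coloured by the comparison in which the gene passed an edgeR adjusted p of 0.05. The horizontal spread (SD 1.44) exceeds the vertical spread (SD 0.49), and the 1686 genes changed in both fill all 4 quadrants.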

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

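Across the settings chosen beforehand and 3 added after the data were seen (total-count scaling, recomputed FPKM and removal of the length trend), the counts of changed genes stayed within 1.5 times those reported. The counts with each library left out in turn were 3913 to 4171 for SoleS against SoleG, 1363 to 1975 for GS against SoleG and 3865 to 4230 for SoleS against GS, with the lone library of a group assumed to vary like the others. GS against SoleG was the most affected: without GS replicate 2, 1339 of its 1983 calls (67.5%) remained called in the same direction. In the other settings the counts were 3883 to 4200, 1547 to 2408 and 3899 to 4203, the lowest each from DESeq2. PK0942 had the widest range of fold changes with a library left out (log2 11.56 to 13.08 for SoleS against SoleG, 15.16 to 18.34 for SoleS against GS). The 18.34 rests on a GS count of 0, so the data set no upper limit to it. Every named gene kept its direction and stayed below an adjusted p of 0.05 in the settings run on counts. Their largest adjusted p was 1.35e-09, for PK4701 in GS against SoleG. The count of genes at least 2-fold higher in GS and higher in SoleS, chosen after the data were seen, was 107 and moved under limma on FPKM. It was 51 with a pseudocount of 1, filtered or not, 65 with 0.1 and 58 with FPKM recomputed from own totals. In these fits 62, 77 and 73 genes were at least 2-fold higher in GS, and several choices changed at once. With edgeR on total counts it was 72 of 88. The 867 genes changed in the same direction in both comparisons against SoleG were 587 to 836 with a library left out, lowest without GS replicate 2, and 661 (DESeq2) to 1175 (total counts) in the others run for it, which were RLE factors, DESeq2, the replicate block, total counts and a different SoleG library for each comparison. The replicate block gave 4142, 1910 and 4162 changed genes and changed no call of a named gene. The replicate numbers did not pair the libraries: the differences between replicates 1 and 2 correlated at -0.04, -0.10 and 0.05 between the groups. The gene list tests, and the alternatives planned for them, were not run because the IDs carry no names. Groups of 2 were too small for a count over other splits of the libraries.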

Other observations

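The tests in this part were chosen after the patterns were seen. The predictions for 3 of the tests were written before their results: the one that left out 1000 genes, the one on pairs of similar abundance and the one on pairs of similar length.

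Genes most strongly higher in SoleS than in SoleG tended to be lower in GS than in SoleG. SoleS lacked glucose as well as holding succinic acid, and no medium lacked both. The part of succinic acid in their rise could therefore not be told apart from that of glucose loss. Of the 20 genes at least 128-fold higher in SoleS than in SoleG, 17 had a lower fitted value in GS than in SoleG, 9 were called lower and 1 higher, and their median log2 difference was -0.37. The 65 genes at least 16-fold higher were less one-sided, with 24 called lower and 18 higher. PK0402, for example, was at 14.3 ± 7.2 CPM in SoleG and 3.04 ± 1.04 CPM in GS (SD, n = 2).

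Reads misassigned from SoleS libraries are 1 technical explanation, since a fixed small share of the SoleS counts would then appear in the glucose libraries. The SoleG counts of the 20 genes ranged from 0.0253% to 0.842% of their SoleS counts, with a chi-square of homogeneity of 180 per degree of freedom. This argues against misassigned reads as the whole source of the SoleG counts. Expression of the genes in SoleG also makes the shares unequal, so the test cannot tell whether misassigned reads add to the difference between SoleG and GS. Scaling as the source of that difference is argued against, since the highest median over TMM, RLE, upper-quartile and total-count scaling was -0.35. A hypothesis left open is that succinic acid, or the medium change that came with it, may lower these genes further while glucose is present, and 2 libraries per group cannot separate medium from culture.

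The split of calls between GS and SoleG moved with the scaling, from 53.3% higher under TMM to 28.9% under total counts. With plain totals the median log2 difference was -0.152. Leaving out the 10 most abundant genes, which held 14.5% of the SoleG and 16.4% of the GS counts, moved it to -0.120, and leaving out 100, with 34.6% and 36.4%, to -0.111. Over the 4 pairs of libraries the last value was -0.122 to -0.096. The 100 genes as the source needed a median within 0.05 of 0. All pairs lay outside that by more than their range, which argues against these 100 as the whole source. The highest pair did not reach the bound of -0.1 first set for excluding them, and the rule used here was chosen after the values were seen. Leaving out 300 genes, with 50.3% of the SoleG and 53.6% of the GS counts, gave -0.053, and -0.063 to -0.040 over the pairs. These values straddle the bound of 0.05, so a set of that size could not be excluded. Leaving out 1000 genes, which held 72.8% and 75.3% of the counts, gave -0.012, but the totals then come mostly from the genes whose median is read, which pulls it towards 0, so this cannot tell whether the shift is spread over many abundant genes. Whether the total RNA per cell differed was not measured, so neither split can be called the true one.

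Genes with neighbouring ID numbers changed together. The Spearman correlation of log2 fold changes over 5108 neighbouring pairs was 0.15 for SoleS against SoleG, 0.12 for GS against SoleG and 0.14 for SoleS against GS. Each had a permutation p of 1e-05, the smallest that 100000 permutations can give, and a Benjamini-Hochberg value of 1e-05 over the 3 comparisons, which share libraries. The correlation was 0.04, 0.03 and 0.04 at 2 positions apart and 0.00, 0.01 and 0.00 at 3 positions apart. PK5146 and PK5147, which fell together in GS, are such a pair. The ID numbers may follow gene order: 47.4% of 5462 runs of 3 IDs repeated the lengths of 3 neighbouring genes of the reference assembly in either direction, against at most 0.0366% in 100 shuffles. Reads of an abundant gene counted in its neighbour would weaken the relation in pairs of similar abundance, but it was at least 0.135 among the 3027 pairs within 4-fold of each other. Tandem copies sharing reads are also argued against, with at least 0.11 after removing the 443 pairs of coding lengths within 10% of each other. Shared regulation of adjacent genes remains a hypothesis, since strand and gene boundaries were not used here.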
